A study of Mus musculus with 9 samples.

How the data were processed

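Gene expression was measured by RNA sequencing in RAW264.7, a mouse macrophage cell line, in 9 libraries that fall into 3 groups of 3. Per the labels, total RNA was extracted with Trizol and made into Illumina libraries. The PBS group was the vehicle control of a model condition that the labels do not name further. The P-Mn@mHSA group received nanoparticles carrying nanoenzymes (materials with enzyme-like activity) under that condition, and the P-Mn/TI@mHSA group received such particles that also carried an inhibitor of TRAF6, an adaptor protein and ubiquitin ligase of Toll-like and interleukin-1 receptor signalling. The labels speak of triplicates and do not say whether these were separate cultures, so the p-values measure the spread between these libraries, which may be technical.

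The deposited table lists 56748 genes with a read count and an FPKM value for each library. Per the file headers, the counts are raw read counts per gene, and the values were whole numbers. The deposited FPKM values equalled the count divided by gene length and by 1 constant per library, with a largest relative deviation of 5.2e-15, so both units hold the same reads. That constant was 0.981 to 1.05 times the total count of the library, and how the authors derived it is not given in the sources used here. Per the submitters' processing notes, cutadapt 1.9 and FastQC were applied and the genome build was GRCm38. The aligner, the counting program and its handling of strand and of reads with several matches are not given in the sources used here. Of 52073 gene identifiers shared with GENCODE M21, an annotation of GRCm38, 1472 had the same start and end in the table. The table's coordinates therefore do not match GENCODE M21, and whether the annotation or the genome build differs was not tested. Only the chromosome of a gene is given. All sample columns of the table belonged to these 9 libraries.

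Total counts were 13994570 to 15543439 per library, and 16685 to 17737 genes had at least 1 count. Genes were tested from the counts with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr, which kept 12454 genes and 99.873 to 99.912% of the counts of each library, libraries were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted to the 9 libraries. The 3 comparisons were P-Mn@mHSA against PBS, P-Mn/TI@mHSA against PBS, and P-Mn/TI@mHSA against P-Mn@mHSA. Tests were two-sided, and genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called changed. A standard error of a log2 fold change is its absolute value divided by the square root of the F statistic, and levels are TMM-normalised read counts scaled to CPM as mean ± SD. The design written before the data were examined assumed FPKM alone and named limma for that case and edgeR for the case that counts were present. limma 3.58.1 on log2(FPKM + 1) was therefore an alternative.

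A set of 41 gene lists was fixed before the data were examined. They cover inflammatory signalling, interferon response, redox and metal handling, metabolism, stress responses, cell cycle and cell death, markers of macrophages and of other cell types, and markers of RNA quality. Lists were tested against all other genes with limma's camera on log2(FPKM + 1), over 11731 genes with a mean FPKM of at least 0.5, with a preset inter-gene correlation of 0.01, lists of at least 5 members, and adjustment over the lists of a comparison. 35 lists could be tested and 6 were too small. Some lists share members, so their calls are not independent. Il1a, Il1b and Il18 are in the pro-inflammatory and inflammasome lists, and Cxcl10 is in the chemokine and interferon lists. Slc7a11 and Chac1 are in the stress response and ferroptosis lists, and Cflar and Bcl2a1d in the NF-kB and apoptosis lists. Every camera call was also computed with an inter-gene correlation estimated from the residuals. The number of members called by edgeR is given over all genes tested and adjusted over the list alone.

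The named genes follow a rule fixed before the data were examined. In each comparison it takes the 8 largest rises and 8 largest falls among changed genes whose groups do not overlap and whose higher group has a mean FPKM of at least 2, without predicted, clone-named or pseudogene entries. It also takes the 3 members with the lowest p in the direction of each called list, and 12 index genes. Arg1, Mrc1 and Nqo1 are index genes that were not tested, because no library had more than 8, 9 and 9 counts of them. By chance, 10% of genes have groups of 3 that do not overlap.

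The fits were tested on simulated counts in which 50 genes were changed at each of 4 folds. In the comparison of P-Mn@mHSA with PBS the model recovered 38% of genes changed 1.25-fold, 68% at 1.5-fold, 82% at 2-fold and 94% at 3-fold, with 16 false calls among 12454 genes. These false calls were a larger share of all calls than the threshold of 0.05. The comparisons of P-Mn/TI@mHSA with PBS and with P-Mn@mHSA had 10 and 7 false calls. In the data a far larger share of genes was called against PBS, 48.5% with P-Mn@mHSA and 54.4% with P-Mn/TI@mHSA. Adjusted p-values depend on that share, so the simulated recovery and false calls need not hold for the comparisons with PBS. Replicates were compared before averaging: their counts differed by 3.74 to 12.8 times sampling noise (chi-square per degree of freedom), so none was a duplicate. Alternatives to the edgeR fit were another filter or scaling, robust moderation, other libraries fitted, other thresholds, DESeq2 1.42.0 and limma on log2(FPKM + 1). For genes, the other pseudocounts, TPM, quantile normalisation and library weights were changed within that limma fit, so they differ from edgeR in test and unit as well. Further alternatives were the set test, a block for the replicate number, and each library left out in turn. Sequence checks used the longest transcript of each gene in GENCODE M21, which had 98.8% of the tested genes, and counted the share of its 50-mers found in another gene. Of 108 named genes, 21 shared at least 10% of their 50-mers with another gene, and their counts are uncertain to the extent that the counting divided such reads.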

Results

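RNA sequencing measured gene expression in 9 libraries of RAW264.7 mouse macrophages, 3 each from cells given PBS, P-Mn@mHSA nanoparticles, or P-Mn/TI@mHSA nanoparticles, which add a TRAF6 inhibitor. Total counts ran from 13994570 to 15543439 per library. The replicates of a group correlated at Pearson r 0.9881 to 0.9915 across genes on log2 CPM, and libraries of different groups at 0.9589 to 0.99. The first principal component held 61.6% of the variance and placed the PBS libraries at -49 to -42 and the particle libraries at 16.8 to 28.3. The second held 9.1% and placed the P-Mn@mHSA libraries below 0, with replicate 2 farthest at -26.7, and the P-Mn/TI@mHSA libraries above 0. Traf6, the target of the inhibitor, was transcribed at 41.6 ± 1.7 CPM (SD, n = 3) in PBS, 45.5 ± 3 in P-Mn@mHSA and 43.8 ± 3.57 in P-Mn/TI@mHSA, and passed the threshold in none of the 3 comparisons (edgeR adjusted p 0.217, 0.481 and 0.763 with unadjusted p 0.141, 0.393 and 0.517). An inhibitor of the protein need not change the transcript.

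The first comparison asked what P-Mn@mHSA did relative to PBS. The antiviral enzyme gene Rsad2 (ENSMUSG00000020641, chromosome 12) rose 18.1-fold, from 13.6 ± 1.08 to 247 ± 12.8 CPM (SD, n = 3 per group), with a log2 fold change of 4.18 ± 0.0986 (SE, edgeR adjusted p 6.36e-18). Adm, which encodes the vasoactive peptide adrenomedullin, rose 18.7-fold from 1.39 ± 0.606 to 26 ± 2.54 CPM (edgeR adjusted p 1.39e-13), and the alarmin cytokine gene Il33 rose 18.5-fold from 2.14 ± 0.236 to 39.6 ± 4.08 CPM. Cmpk2, a mitochondrial nucleotide kinase gene, rose 9.52-fold and Mgarp, a mitochondrial protein gene, 11-fold. The collagen gene Col5a3 fell 15.4-fold, from 138 ± 0.884 to 8.94 ± 1.52 CPM (log2 fold change -3.95 ± 0.115, edgeR adjusted p 1.61e-16). Ccr7, a chemokine receptor gene, fell 21.9-fold from 4.73 ± 0.503 CPM (log2 fold change -4.45, and -5.37 without P-Mn@mHSA replicate 1), Batf, a transcription factor gene, 13.1-fold, the cytokine gene Il36g 9.47-fold, and Prss35, Stfa3, Gstp3 and Gstt4 fell 90.1-fold, 30.7-fold, 16-fold and 9.85-fold from 9.1 ± 3.53, 15.9 ± 1.58, 9.37 ± 1.51 and 6.46 ± 1.46 CPM. The rRNA gene n-R5s88 had no count in PBS and was at least 4.08-fold higher, against a floor of 3 counts per library. H3c3, a histone gene that shares 47% of its 50-mers with other genes, rose 10.6-fold at 1.53 ± 0.403 CPM. In several of these genes the lower group held few reads. With P-Mn@mHSA, Prss35 ran from 0.07 to 0.135 CPM, Ccr7 from 0 to 0.406 and Batf from 0.135 to 0.355. Stfa3, Gstp3, Gstt4 and Il36g reached at most 0.837, 0.812, 0.812 and 0.71 CPM there. With PBS, H3c3 ran from 0.068 to 0.203 CPM and Mgarp from 0.273 to 0.878. The sizes of these folds are therefore uncertain. Gapdh rose 10.3-fold, but with 7579 counts in replicate 2 against 517 and 537 in the other P-Mn@mHSA libraries, and without replicate 2 its log2 fold change dropped from 3.36 to 0.91 (edgeR adjusted p 4.02e-08). Gapdh shares 27.6% of its 50-mers with other genes.

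Of 12454 genes tested, 6035 changed, 3028 higher and 3007 lower, and at 2-fold or more 381 were higher and 706 lower. Of the changed genes 50.2% were higher under edgeR, 53% with limma on log2(FPKM + 1) and 37.2% with limma after rescaling to TPM. Leaving out 1 library gave 5243 to 6074 changed genes, and each of the 48 changed genes that the naming rule selected passed in all 9 such fits.

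Interferon-stimulated genes were the list with the lowest p: 48 of 53 were higher, 1 lower and 4 not past the threshold (49 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.98 (camera adjusted p 2.73e-20, and 0.189 with an estimated correlation). Rsad2 and Cmpk2 led it, and Oasl2, an antiviral oligoadenylate synthetase-like gene, rose 4.81-fold. Among antigen presentation genes 16 of 29 were higher and 2 lower (16 and 2 adjusted over the list alone, camera adjusted p 0.0135, 0.124 after quantile normalisation, and 0.364 with an estimated correlation). Without PBS replicate 2, 10 antigen presentation genes were higher. The immunoproteasome subunit genes Psmb10 and Psmb9 rose 2.14-fold and 1.86-fold and the peptide transporter gene Tap1 1.79-fold. Glycolysis and hypoxia genes were higher in 32 of 37 and lower in 3 (33 and 3 adjusted over the list alone), with a median of 0.68 (camera adjusted p 1.33e-12, and 0.156 with an estimated correlation). In this list Ndrg1, a hypoxia-inducible gene, rose 5.8-fold from 51.5 ± 6.13 to 299 ± 23.4 CPM, Ddit4, an mTORC1 inhibitor gene, rose 4.98-fold, and the phosphofructokinase gene Pfkl 3.16-fold. Stress genes followed: 29 of 51 genes of the integrated stress and unfolded protein responses were higher and 4 lower (31 and 4 adjusted over the list alone, median 0.3, camera adjusted p 8.63e-06, and 0.48 with an estimated correlation). The stress transcription factor gene Atf3 rose 7.36-fold from 35.3 ± 6.73 to 260 ± 18.1 CPM, and the eIF2α phosphatase subunit gene Ppp1r15a 4.39-fold. Immediate early genes were higher in 21 of 32 and lower in 4 (22 and 4 adjusted over the list alone, median 0.48, camera adjusted p 1.74e-06, and 0.364 with an estimated correlation). Egr1 rose 5.13-fold and the phosphatase gene Dusp5, which shares 20.6% of its 50-mers, 2.96-fold. Of 33 p53 target genes 16 were higher and 5 lower (16 and 5 adjusted over the list alone, camera adjusted p 0.0135, and 0.226 with an estimated correlation). Plk2, Plk3 and the cell cycle inhibitor gene Cdkn1a rose 7.52-fold, 3.29-fold and 3.04-fold.

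G2/M genes were lower in 28 of 52 and higher in 10 (28 and 10 adjusted over the list alone), with a median of -0.22 (camera adjusted p 0.00239, and 0.615 with an estimated correlation). The mitotic genes Cenpe, Mki67 and Smc4 fell 3.93-fold, 2.42-fold and 2.32-fold. Cholesterol biosynthesis genes were lower in 18 of 25 and higher in 2 (18 and 2 adjusted over the list alone, median -0.32, camera adjusted p 0.000112, and 0.364 with an estimated correlation). Hmgcs1, Stard4 and Msmo1 fell 1.55-fold, 1.49-fold and 1.43-fold. NF-kB feedback and target genes were lower in 13 of 30 and higher in 5 (15 and 5 adjusted over the list alone, median -0.2, camera adjusted p 0.0275, and 0.892 with an estimated correlation). The caspase-8 regulator gene Cflar, the NF-kB subunit gene Rel and the ubiquitin ligase gene Birc3 fell 2.09-fold, 1.74-fold and 1.63-fold. The NF-kB list call was lost without PBS replicate 3 (camera adjusted p 0.081), P-Mn@mHSA replicate 1 (0.0643) or P-Mn@mHSA replicate 2 (0.0533). Oxidative phosphorylation genes were higher in 34 of 75 and lower in 2 (34 and 2 adjusted over the list alone, median 0.15, camera adjusted p 0.00224, and 0.919 with an estimated correlation). Atp5g1, Atp5g3 and Ndufa8 rose 1.44-fold, 1.36-fold and 1.32-fold. The oxidative phosphorylation call was lost without P-Mn@mHSA replicate 2 (camera adjusted p 0.127, median 0.0908), with quantile normalisation (0.448), with genes of mean FPKM of at least 5 (0.105) and with fry (0.0894).

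Inflammatory and redox genes split. The inducible nitric oxide synthase gene Nos2 fell 2.31-fold, from 371 ± 13.1 to 161 ± 13.3 CPM (edgeR adjusted p 1.14e-11), and Il1b fell 3.07-fold, from 37.7 ± 2.73 to 12.3 ± 1.74 CPM, while Tnf rose 1.26-fold, from 842 ± 65.3 to 1060 ± 77.4 CPM (edgeR adjusted p 0.000496). Il6 did not pass (log2 fold change 0.14, edgeR adjusted p 0.545), and its direction turned without P-Mn@mHSA replicate 2 (-0.03). The 24 pro-inflammatory mediators held 10 higher and 10 lower, with a median of 0.11 and a mean of -0.17, and the list did not pass (camera adjusted p 0.658). The haem oxygenase gene Hmox1 rose 1.75-fold, from 428 ± 26 to 748 ± 32.8 CPM, and the metallothionein gene Mt1 1.52-fold, while the mitochondrial superoxide dismutase gene Sod2 fell 1.93-fold, from 274 ± 19.5 to 142 ± 6.96 CPM, and the catalase gene Cat did not pass (edgeR adjusted p 0.3). Among NRF2 target genes 15 of 35 were higher and 9 lower, among antioxidant enzymes 14 of 28 and 4, among metal-ion response genes 7 of 28 and 6, and among alternative activation markers 6 of 20 and 5, and none of these lists passed by camera (adjusted p 0.637, 0.409, 0.82 and 0.637, in that order).

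**Figure D1:**
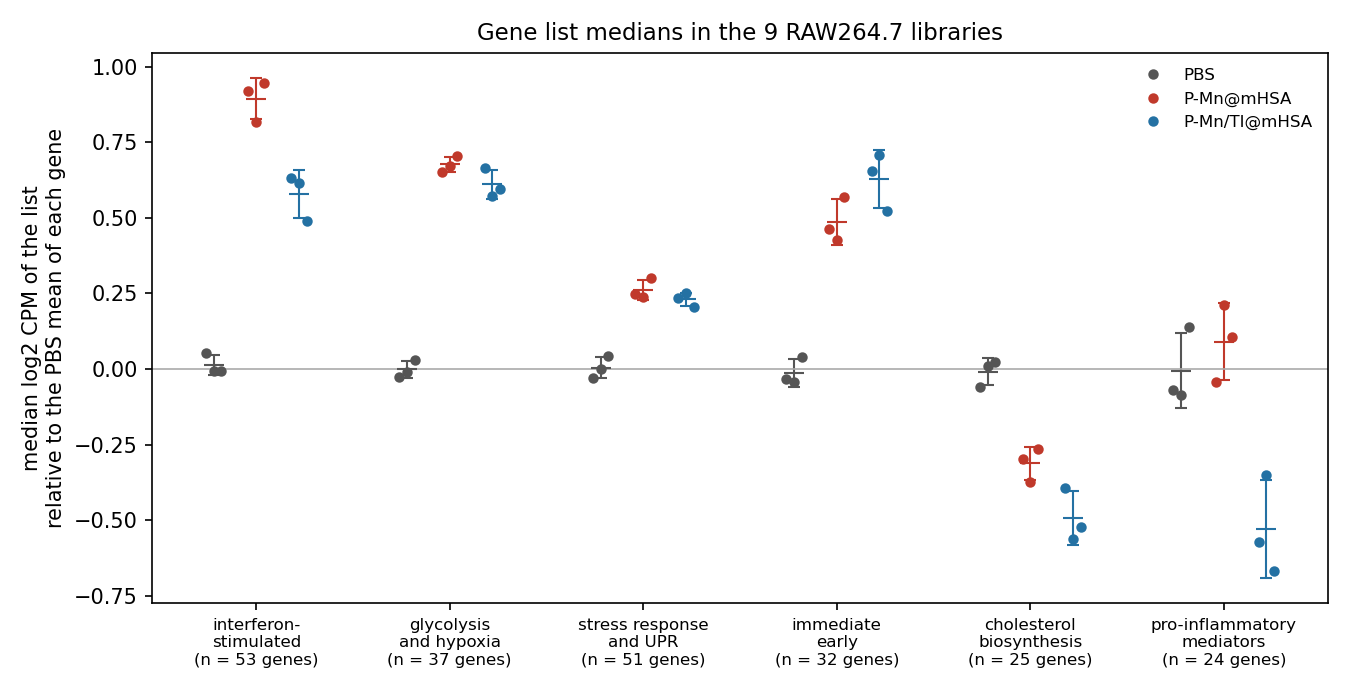
Median log2 CPM of 6 gene lists in each library, relative to the PBS mean of each gene. Points are libraries, horizontal lines group means and bars SD (n = 3), and the interferon list lay at 0.816 to 0.946 in P-Mn@mHSA and 0.489 to 0.632 in P-Mn/TI@mHSA.

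The next comparison asked what the particles with the TRAF6 inhibitor did relative to PBS. Adm rose 17.8-fold and Il33 11.1-fold, and Pdcd1, which encodes the inhibitory receptor PD-1, rose 11.1-fold from 9.9 ± 2.04 to 110 ± 4.41 CPM (SD, n = 3 per group, log2 fold change 3.47 ± 0.11, SE, edgeR adjusted p 4.72e-16). Csf3, the gene of the granulocyte growth factor G-CSF, fell 7.16-fold from 699 ± 74.8 to 97.6 ± 7.72 CPM (edgeR adjusted p 9.03e-17), and the chemokine gene Ccl22 fell 11.9-fold from 114 ± 6.42 to 9.55 ± 0.502 CPM. Il1b fell 7.8-fold to 4.81 ± 0.583 CPM (edgeR adjusted p 1.91e-13), Nos2 2.42-fold to 153 ± 13.3 CPM and Il6 1.69-fold, from 10.4 ± 1.45 to 6.16 ± 1.6 CPM (edgeR adjusted p 0.00224). Pmepa1, Rsad2, the immediate early gene Fosb and Mgarp rose 10.7-fold, 10.1-fold, 8.55-fold and 7.83-fold, and n-R5s88 was at least 3.15-fold higher. Particles without the inhibitor had moved Pdcd1, Csf3, Ccl22, Pmepa1 and Fosb in the same direction. In the P-Mn@mHSA libraries Pdcd1 ran from 83.3 to 99.6 CPM, Csf3 from 124 to 139 and Ccl22 from 12.1 to 15.8. Pmepa1 ran from 17.7 to 24.3 CPM there and Fosb from 12.4 to 17.1. Col5a3, Il36g and Stfa3 fell 15.1-fold, 12.5-fold and 33.5-fold, and Ccr7, Gstp3, Batf and Prss35 fell to 0.0441, 0.224, 0.0876 and 0.292 CPM, with at least 1 library at 0 counts. With P-Mn/TI@mHSA, Il36g ran from 0.201 to 0.474 CPM and Stfa3 from 0.136 to 1.005, so the sizes of their folds rest on few reads. The log2 fold change of Stfa3 went from -5.07 to -6.26 without P-Mn/TI@mHSA replicate 3, that of Gstp3 from -5.34 to -6.43 without the same library, and that of Batf from -5.01 to -6.23 without P-Mn/TI@mHSA replicate 2.

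Of the 12454 genes 6781 changed, 3378 higher and 3403 lower, and 330 were higher and 912 lower by 2-fold or more. Of the 47 changed genes under the naming rule, 45 passed in all 9 fits that left out 1 library. The others were Tnf, which rose 1.17-fold (edgeR adjusted p 0.00903, 0.0574 without PBS replicate 2 and 0.057 without P-Mn/TI@mHSA replicate 2), and Cat, which fell 1.16-fold (0.0217, 0.0656 without PBS replicate 2, 0.11 without PBS replicate 3, 0.111 without P-Mn/TI@mHSA replicate 1 and 0.0562 without P-Mn/TI@mHSA replicate 2).

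Pro-inflammatory mediators were lower in 13 of 24 and higher in 7 (13 and 7 adjusted over the list alone, median -0.58, camera adjusted p 0.0336, and 0.928 with an estimated correlation). Csf3 and Il1b led it, and the siderophore-binding protein gene Lcn2 fell 3.86-fold. This call was lost without PBS replicate 3 (camera adjusted p 0.0519), without P-Mn/TI@mHSA replicate 3 (0.0725) and on ranks (0.116). NF-kB feedback and target genes were lower in 17 of 30 and higher in 2 (17 and 2 adjusted over the list alone, median -0.21, camera adjusted p 0.00201, and 0.532 with an estimated correlation). Cflar, Rel and Birc3 fell 2.33-fold, 1.93-fold and 1.72-fold. Among chemokines 5 of 14 were higher and 7 lower, among inflammasome and pyroptosis genes 5 of 26 and 12, and among components of TRAF6 and Toll-like receptor signalling 12 of 43 and 13. These 3 lists did not pass (camera adjusted p 0.814, 0.0708 and 0.838). Cholesterol biosynthesis genes were lower in 20 of 25 and higher in 1 (21 and 1 adjusted over the list alone, median -0.49, camera adjusted p 1.16e-06, and 0.413 with an estimated correlation). Hmgcs1, the desaturase gene Sc5d and Msmo1 fell 2.11-fold, 1.78-fold and 1.65-fold.

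Glycolysis and hypoxia genes were higher in 31 of 37 and lower in 3 (31 and 3 adjusted over the list alone, median 0.61, camera adjusted p 8.2e-10, and 0.263 with an estimated correlation). Ndrg1, Ddit4 and Pfkl rose 5.66-fold, 4.25-fold and 3.32-fold. Interferon-stimulated genes were higher in 34 of 53 and lower in 4 (34 and 5 adjusted over the list alone, median 0.56, camera adjusted p 1.61e-07, and 0.423 with an estimated correlation). Rsad2 reached 137 ± 18.3 CPM, Cmpk2 rose 5.39-fold and the chemokine gene Cxcl10 3.26-fold (32.5 to 34.8 CPM in P-Mn@mHSA, 36.4 to 40.3 in P-Mn/TI@mHSA). Immediate early genes were higher in 22 of 32 and lower in 8 (22 and 8 adjusted over the list alone, median 0.66, camera adjusted p 7.82e-05, and 0.508 with an estimated correlation). Atf3, Arc and Egr1 rose 6.33-fold, 5.53-fold and 4.8-fold. Genes of the integrated stress and unfolded protein responses were higher in 29 of 51 and lower in 6 (30 and 6 adjusted over the list alone, median 0.21, camera adjusted p 0.000467, 0.0569 after quantile normalisation, and 0.619 with an estimated correlation). Ppp1r15a rose 4.11-fold. G1/S genes were higher in 27 of 46 and lower in 6 (27 and 6 adjusted over the list alone, median 0.22, camera adjusted p 0.00766, and 0.413 with an estimated correlation). The replication helicase genes Mcm2, Mcm5 and Mcm7 rose 1.62-fold, 1.61-fold and 1.52-fold, Mcm7 with 34.3% of its 50-mers in other genes. Oxidative phosphorylation genes were higher in 33 of 75 and lower in 5 (33 and 5 adjusted over the list alone, median 0.11, camera adjusted p 0.0336, and 0.928 with an estimated correlation). Atp5g1, Atp5g3 and Cyc1 rose 1.45-fold, 1.36-fold and 1.33-fold. The call was lost without PBS replicate 2 (camera adjusted p 0.172, median 0.0759), PBS replicate 3 (0.0519) or P-Mn/TI@mHSA replicate 3 (0.226, median 0.0712) and with quantile normalisation (0.795), genes of mean FPKM of at least 5 (0.464) and fry (0.152). Hmox1 rose 1.48-fold and Mt1 1.68-fold, and Sod2 fell 1.91-fold.

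The last comparison set P-Mn/TI@mHSA against P-Mn@mHSA and asked what the TRAF6 inhibitor added. Isg20, an interferon-induced exonuclease gene, fell 2.27-fold from 120 ± 4 to 52.8 ± 4.69 CPM (SD, n = 3 per group, log2 fold change -1.18 ± 0.0793, SE, edgeR adjusted p 1.23e-08). The nucleic acid sensor gene Zbp1 fell 1.88-fold from 174 ± 7.93 to 92.4 ± 6.26 CPM (edgeR adjusted p 1.24e-07), Il1b fell 2.54-fold from 12.3 ± 1.74 to 4.81 ± 0.583 CPM (edgeR adjusted p 8.48e-06), Il1a 2.49-fold, and the chemokine gene Ccl5 1.52-fold from 407 ± 4.04 to 269 ± 8.76 CPM. The guanylate-binding protein gene Gbp3 and Ifi202b fell 2.55-fold and 2.04-fold. Ifit3b, Ifit3 and Phf11b fell 2.9-fold, 2.54-fold and 2.03-fold, each with 45 to 51.5% of its 50-mers in other genes. The urokinase gene Plau rose 1.46-fold from 154 ± 17.1 to 225 ± 4.25 CPM (edgeR adjusted p 0.000105), Tmem26 1.46-fold and Rnf157 1.42-fold. The naming rule also selected Ccdc116, Ankle1, Zfp316, Oip5 and Pou2f2 as rises, and each lost its call when single libraries were left out. Their edgeR adjusted p was 0.0564 and 0.191 for Ccdc116 and Zfp316 without P-Mn@mHSA replicate 2. It was 0.158 and 0.083 for Ankle1 and Pou2f2 without P-Mn/TI@mHSA replicate 1, and 0.122 for Oip5 without P-Mn/TI@mHSA replicate 3. Tnf, Nos2, Sod2, Cat and Mt1 did not pass (edgeR adjusted p 0.424, 0.638, 0.946, 0.42 and 0.269).

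Of 12454 genes 476 changed, 184 higher and 292 lower, and 2 and 18 of them by 2-fold or more, with 2502 genes at an unadjusted p under 0.05. This count moved with single libraries, to 129 without P-Mn/TI@mHSA replicate 1, 213 without P-Mn/TI@mHSA replicate 3, 272, 202 and 794 without P-Mn@mHSA replicates 1, 2 and 3. Of the 46 changed genes under the naming rule 22 passed in all 9 such fits. The share of higher genes was 38.7% with edgeR, 25.7% with limma on log2(FPKM + 1), 25.5% with limma after rescaling to TPM and 21.7% with limma after quantile normalisation. Il6 fell 1.86-fold (edgeR adjusted p 0.011), which was lost without P-Mn@mHSA replicate 2 (0.0589) or P-Mn/TI@mHSA replicate 1 (0.0857). Hmox1 fell 1.18-fold (edgeR adjusted p 0.0305), which was lost without P-Mn@mHSA replicates 1 (0.0703) or 3 (0.0674) or P-Mn/TI@mHSA replicates 1 (0.09), 2 (0.0531) or 3 (0.144).

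Interferon-stimulated genes were lower in 36 of 53, with 17 not past the threshold (41 lower adjusted over the list alone), and their median log2 fold change was -0.48 (camera adjusted p 1.77e-33, and 0.059 with an estimated correlation). Of those 36 genes, 34 had been higher in P-Mn@mHSA than in PBS, a share close to the 48 of 53 in the whole list. With both particles 34 of the 53 genes were higher than PBS. Antigen presentation genes were lower in 9 of 29 (14 adjusted over the list alone, median -0.21, camera adjusted p 3.94e-09, and 0.059 with an estimated correlation). Psmb9 and Psmb10 fell 1.45-fold and 1.33-fold, and H2-T22, which shares 58.5% of its 50-mers, 1.34-fold. Pro-inflammatory mediators were lower in 10 of 24 (13 adjusted over the list alone, median -0.44, camera adjusted p 3.94e-09, and 0.202 with an estimated correlation), and Lcn2 fell 1.56-fold. Of those 10, 5 had been higher and 4 lower in P-Mn@mHSA than in PBS. Chemokines were lower in 5 of 14 (7 adjusted over the list alone, median -0.29, camera adjusted p 0.000457, and 0.395 with an estimated correlation), and the list missed the threshold with fry (adjusted p 0.0574). Inflammasome and pyroptosis genes were lower in 8 of 26 (9 lower and 1 higher adjusted over the list alone, median -0.18, camera adjusted p 0.000554, and 0.0897 with an estimated correlation). The cytokine gene Il18, which like Il1a and Il1b is also in the pro-inflammatory list, fell 1.48-fold. Cholesterol biosynthesis genes were lower in 4 of 25 (12 adjusted over the list alone, median -0.18, camera adjusted p 3.03e-07, and 0.148 with an estimated correlation). All 4 were already lower in P-Mn@mHSA than in PBS, as were 18 of the 25 in the whole list, and Hmgcs1 fell 1.36-fold. Several of these counts moved with single libraries. Without P-Mn@mHSA replicate 1, 4 antigen presentation and 2 cholesterol genes were lower. Without P-Mn@mHSA replicate 2, 1 chemokine (list median -0.184), 3 inflammasome and 2 cholesterol genes were lower, and without P-Mn@mHSA replicate 3, 3 chemokines. Leaving out P-Mn/TI@mHSA replicate 1 gave 4 antigen presentation genes, 2 chemokines, 3 inflammasome and 2 cholesterol genes, and leaving out P-Mn/TI@mHSA replicate 3 gave 5, 1, 5 and 1.

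Cell cycle lists were higher. G1/S genes were higher in 6 of 46 and lower in 1 (13 and 1 adjusted over the list alone, median 0.14, camera adjusted p 3.61e-06, and 0.0897 with an estimated correlation). The uracil-DNA glycosylase gene Ung rose 1.36-fold from 34 ± 1.3 to 46.1 ± 2.59 CPM (edgeR adjusted p 0.00395). The G1/S count fell to 1 without P-Mn@mHSA replicate 2 or P-Mn/TI@mHSA replicate 1, and to 3 and 2 without P-Mn/TI@mHSA replicates 2 and 3. G2/M genes were higher in 3 of 52 (11 adjusted over the list alone, median 0.11, camera adjusted p 1.28e-05, and 0.262 with an estimated correlation). These 3 genes were Cdca8, Racgap1 and Bub1b, and each call was lost with single libraries left out. Cdca8 was lost without P-Mn/TI@mHSA replicate 3 (edgeR adjusted p 0.0663). Racgap1 was lost without P-Mn@mHSA replicate 2 (0.0781) or P-Mn/TI@mHSA replicates 1 (0.107) or 3 (0.105). Bub1b was lost without P-Mn@mHSA replicates 1 (0.0588) or 2 (0.114) or P-Mn/TI@mHSA replicates 1 (0.154), 2 (0.0519) or 3 (0.104). Without P-Mn@mHSA replicate 2, P-Mn@mHSA replicate 3 and P-Mn/TI@mHSA replicate 3 the G2/M count was 1, 5 and 0, with a median of 0.0669 in the second of these fits.

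The other called lists were lower. Mitochondrially encoded genes were lower in 4 of 14 (6 adjusted over the list alone, median -0.26, camera adjusted p 0.0117, 0.054 without P-Mn/TI@mHSA replicate 1, and 0.586 with an estimated correlation). The mitochondrial rRNA gene mt-Rnr2 fell 1.67-fold. P-Mn@mHSA replicate 2 carried most of the fall of this list, since the median was -0.0943 without it. The counts were 1, 1 and 2 without P-Mn@mHSA replicate 2, P-Mn/TI@mHSA replicate 1 and P-Mn/TI@mHSA replicate 3. The call of mt-Atp6 was lost in the first 2 of these fits (edgeR adjusted p 0.0692 and 0.104), and that of mt-Co3 in all 3 (0.0655, 0.107 and 0.0513). Of their 50-mers, mt-Atp6 and mt-Co3 share 99.2% and 100% with other genes, so their counts are uncertain, and mt-Rnr2 shares 0.977%. Ferroptosis regulators were lower in 7 of 27 (8 adjusted over the list alone, median -0.04, camera adjusted p 0.012, and 0.262 with an estimated correlation). Their count fell to 3 without P-Mn@mHSA replicates 1 or 2 and to 0, 4 and 2 without P-Mn/TI@mHSA replicates 1, 2 and 3. Their median was -0.0689 and -0.0815 without P-Mn@mHSA replicates 2 and 3, and -0.0628, -0.0231 and -0.0575 without P-Mn/TI@mHSA replicates 1, 2 and 3. Stress response genes were lower in 4 of 51 (4 adjusted over the list alone, median -0.06, camera adjusted p 0.0159, and 0.654 with an estimated correlation). The call was lost without P-Mn@mHSA replicate 3 (0.28) or P-Mn/TI@mHSA replicate 3 (0.213, median -0.0264). The stress count was 2 and 1 without P-Mn@mHSA replicates 1 and 2, and 0, 2 and 2 without P-Mn/TI@mHSA replicates 1, 2 and 3. NF-kB target genes were lower in 2 of 30 (2 adjusted over the list alone, median -0.11, camera adjusted p 0.0228, and 0.583 with an estimated correlation). These 2 were Slfn2, a call lost without P-Mn/TI@mHSA replicate 1 (edgeR adjusted p 0.0619), and Ier3, and the list was lost without P-Mn@mHSA replicate 3 (camera adjusted p 0.17) or P-Mn/TI@mHSA replicate 3 (0.199, median -0.0584). Ribosomal protein genes (1 of 77 higher; adjusted over the list alone 0, with 2 higher and 13 lower at an unadjusted p under 0.05) had a median of -0.07 (camera adjusted p 0.0139, and 0.858 with an estimated correlation). The list turned direction without P-Mn@mHSA replicate 2 (0.482, median 0.00528), had medians of -0.147 and -0.126 without P-Mn@mHSA replicate 3 and P-Mn/TI@mHSA replicate 3, and was lost without P-Mn/TI@mHSA replicates 1 (0.138) or 2 (0.276). Apoptosis regulators had 0 of 39 past the threshold by edgeR, adjusted over all genes or over the list alone, with 6 lower and 2 higher at an unadjusted p under 0.05 (median -0.1, camera adjusted p 0.0357, and 0.164 with an estimated correlation). That call was lost without P-Mn@mHSA replicates 2 (0.056) or 3 (0.112) or P-Mn/TI@mHSA replicates 1 (0.054) or 3 (0.107). With library weights camera called 8 of the 14 lists and lost the NF-kB (adjusted p 0.115), stress response (0.0507), apoptosis (0.115), ferroptosis (0.0507), mitochondrially encoded (0.103) and ribosomal protein (0.165) lists. After rescaling to TPM it lost the stress response (0.0737) and apoptosis (0.0728) lists, and after quantile normalisation the ribosomal protein list (0.506). Fry lost the NF-kB (0.143), stress response (0.204), mitochondrially encoded (0.202) and ribosomal protein (0.663) lists. Of 43 components of TRAF6 and Toll-like receptor signalling 1 was lower, and the list did not pass (camera adjusted p 0.553).

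**Figure D2:**
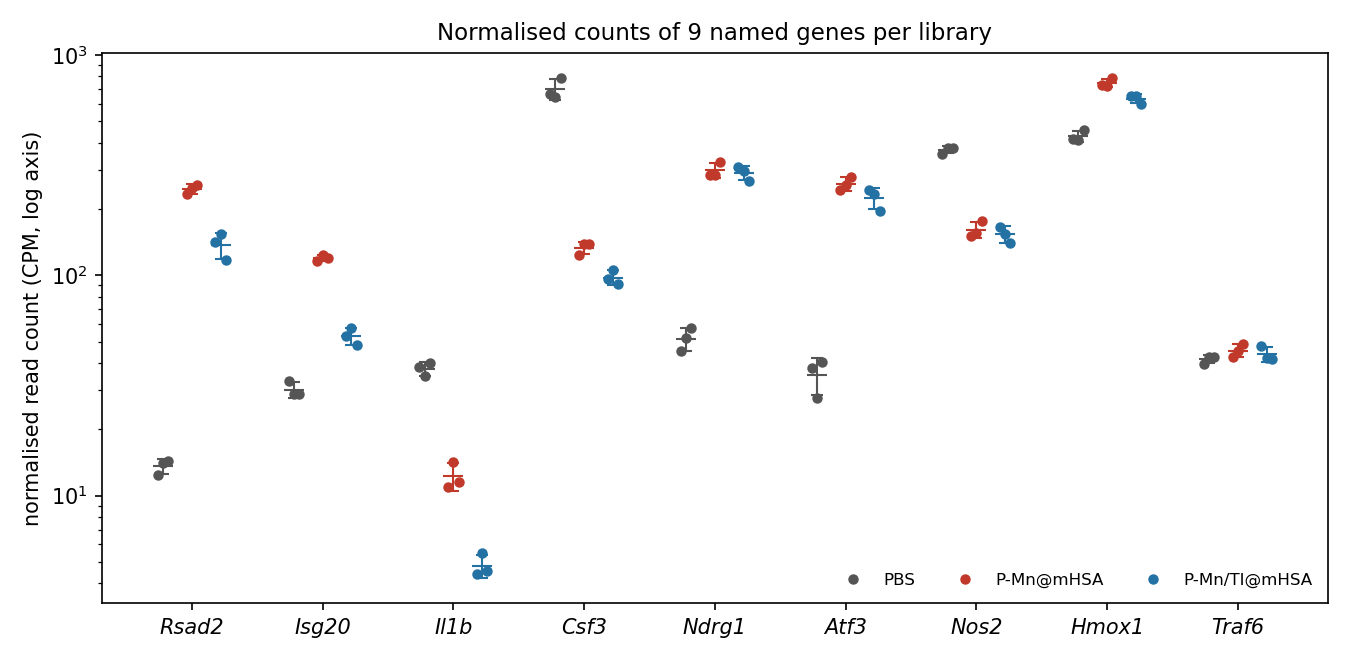
Normalised read counts (CPM, log axis) of 9 named genes in each library. Points are libraries, horizontal lines group means and bars SD (n = 3), and Isg20 averaged 120 CPM in P-Mn@mHSA and 52.8 in P-Mn/TI@mHSA while the group means of Traf6 were 41.6 to 45.5.

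Across the 12454 genes, the fold changes of both particles against PBS correlated at Pearson r 0.906 and Spearman rho 0.889, where genes are not independent replicates. Both comparisons use the same PBS libraries, and unchanged groups simulated against them gave r 0.501 and rho 0.45. The covariance was 0.432 against 0.0215 in the simulation, a difference of 0.411. Both particles raised 2585 genes and lowered 2584, where independent lists would share 821.3 and 821.6 and simulated unchanged groups shared 0.05 on average, and 5 genes went opposite ways. With 3 PBS libraries, no split leaves at least 2 on each side, so part of the excess of shared calls may come from the shared libraries. For the covariance, the simulated spread of those libraries gave 0.0215 and so accounts for little of the 0.432. A deviation common to all 3 PBS libraries was not simulated. Of the 476 genes that differed between the particles, 311 had also changed in P-Mn@mHSA against PBS, 167 in the opposite and 144 in the same direction, and 165 had not. Genes higher in P-Mn@mHSA than in PBS and lower again in P-Mn/TI@mHSA numbered 126, where independent lists would share 71, and genes lower and then higher numbered 41, against 44.43. Genes that moved further numbered 63 upward and 81 downward, against 44.74 and 70.5. These comparisons share the P-Mn@mHSA libraries, which alone gives simulated fold changes a correlation of -0.499 (observed -0.123) and a covariance of -0.0214 (observed -0.025). The observed covariance differed by -0.00363 from that of the sharing alone. Simulated unchanged groups gave 0.1 genes of opposite direction on average. With no change in any group few genes can be called, so this value does not tell how many of the 167 come from the sharing. The same holds for the 0.05 genes above.

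Over the 35 lists, camera called 10, 9 and 14 lists in the 3 comparisons with the preset correlation and 0 in each with an estimated correlation, where 3, 2 and 7 lists had an unadjusted p under 0.05. Fry, which tests whether a list's genes move on balance in the same direction and does not set them against other genes, called 22, 17 and 11 lists.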

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

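Removing mitochondrially encoded genes and Gapdh before scaling (6036, 6783 and 486 changed genes, where the comparisons had 6035, 6781 and 476) and camera on log2 CPM were chosen after seeing the data; every other setting was planned. P-Mn@mHSA and P-Mn/TI@mHSA against PBS fell to 3507 and 4048 changed genes when only genes of mean FPKM of at least 5 were tested, which tests fewer genes, and to 1087 and 1242 when a log2 fold change of at least 1 was required, and stayed within 1.5 times under the other settings (5243 to 6074 and 6039 to 7139 without 1 library). P-Mn/TI@mHSA against P-Mn@mHSA gave 791 with no filter, 20 at a log2 fold change of at least 1, 122 at an adjusted p under 0.01, 144, 140 and 148 with limma at a pseudocount of 1, 0.1 and 0.5, 94 with limma after rescaling to TPM, 92 with limma after quantile normalisation and 129 to 794 without 1 library (129 without P-Mn/TI@mHSA replicate 1, 794 without P-Mn@mHSA replicate 3). Leaving out a library moved the count both ways, so fewer samples alone did not set it. Beyond the stricter thresholds the cause of these shifts was not tested. DESeq2 gave 5851, 6593 and 665. The replicate block gave 5846, 6609 and 312, and with it camera called the same 10, 9 and 14 lists. Replicates share only a number: deviations of same-numbered libraries correlated at -0.066 to 0.061 and those of different numbers at -0.098 to 0.1, and 3 of 9 libraries had their best match in another group at their own number, where chance gives 3. The fold change correlation was 0.865 with a pseudocount of 0.1 and 0.867 to 0.906 without 1 library. Genes moved back by P-Mn/TI@mHSA (167) numbered 82 with limma, 83 at a pseudocount of 0.1, 59 with limma after quantile normalisation and 81 to 191 without 1 library, and genes moved further (144) numbered 32, 31, 17 and 24 to 229. Camera called 0, 0 and 0 lists with an estimated correlation and 8 between the particles with library weights, fry called 22 and 17 against PBS, and without 1 library camera called 8 to 10, 7 to 10 and 12 to 14. The largest shift of the median of all genes was -0.0778 (log2), after rescaling to TPM. Robust moderation was run for genes and not run for camera.

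Values that changed sign were not past the threshold in either fit, except for the ribosomal protein list. Traf6 in P-Mn/TI@mHSA against PBS went to -0.0169 at a mean FPKM of at least 5. Sod2 between the particles went to -0.00399 there, -0.00258 with library weights, and -0.0281 to 0.0346 without 1 library (-0.00402 without P-Mn/TI@mHSA replicate 2). Nos2 between the particles ranged from -0.13 to 0.000431 without 1 library, and Il6 in P-Mn@mHSA against PBS from -0.0307 to 0.278, with -0.0468 under library weights. The ribosomal protein list between the particles had a camera adjusted p of 3.52e-06 to 0.482 without 1 library, and the cause was not tested. Fold changes varied with gene length over all genes. Between the particles the decile of shortest genes had a median log2 fold change of -0.0985 (Spearman rho 0.108 over all genes). Against PBS the decile of longest genes had medians of -0.213 with P-Mn@mHSA and -0.224 with P-Mn/TI@mHSA. A length trend was removed only for the interferon list and the glycolysis and hypoxia list. Over all named genes, 1335 of the values without 1 library kept direction and side of the threshold, 79 lost the call, 4 gained it and 4 changed sign, with 919, 20, 5 and 1 over all lists, and under the other settings 2258, 223, 7 and 4 for genes and 1368, 56, 40 and 0 for lists. Arg1, Mrc1 and Nqo1 reached 8, 9 and 9 counts at most, and low transcription and limited depth were not separated for them.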

Other observations

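The tests of 1 library alone, of near-identical copies and of depth were chosen after their results were seen, as were the genes named in this paragraph and the next. Of 682 long non-coding RNAs tested, 198 (29%) were lower with P-Mn@mHSA than with PBS, 42 (6.16%) higher and 442 not past the threshold, with a median log2 fold change of -0.38. Of 10859 protein-coding genes 2719 (25%) were lower and 2871 (26.4%) higher. No set test was run on the non-coding group. With P-Mn/TI@mHSA 187 were lower and 48 higher, and between the particles 1 and 2. On log2 CPM the median with P-Mn@mHSA was -0.372 with TMM or median-of-ratios scaling, -0.395 with upper quartiles and -0.445 with total counts. It was -0.313 on log2(TPM + 1), -0.143 on log2(FPKM + 1) and -0.0598 after quantile normalisation of the latter, where the unit and pseudocount differ as well. The nuclear transcripts Malat1 and Neat1 fell from 367.4 ± 107 to 64.69 ± 9.69 CPM (SD, n = 3; log2 fold change -2.51, edgeR adjusted p 1.04e-11) and from 446.9 ± 63.2 to 155.7 ± 7.6 CPM (-1.52, edgeR adjusted p 2.43e-12).

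Macrophage identity markers did not move together: with P-Mn@mHSA 10 of 27 were higher and 9 lower, and with P-Mn/TI@mHSA 9 and 11 (camera adjusted p 0.658 and 0.714). Adgre1, which encodes F4/80, fell from 104.1 ± 9.46 to 26.99 ± 1.97 CPM with P-Mn@mHSA (log2 fold change -1.95), the lysozyme gene Lyz2 from 1848 ± 2.63 to 578.8 ± 51.7 CPM (-1.67) and the integrin gene Itgam from 160.8 ± 10.6 to 63.57 ± 3.58 CPM (-1.34), while the growth factor receptor gene Csf1r rose from 1645 ± 86.7 to 2120 ± 179 CPM (0.37). Markers of T and NK cells, neutrophils and epithelium had a median of 0 CPM in each group, and those of B cells, fibroblasts and endothelium medians of at most 0.128 CPM. Single members exceeded 10 CPM: 1 for T and NK cells, 1 for neutrophils, 0 for epithelium, 2 for B cells, 2 for fibroblasts and 1 for endothelium. Dendritic cell markers had medians of 0.581, 0.692 and 0.355 CPM in PBS, P-Mn@mHSA and P-Mn/TI@mHSA and 4 of 18 members over 10 CPM, and the list did not pass (camera adjusted p 0.82, 0.671 and 0.0711 in the 3 comparisons). The mitochondrial genes split: with P-Mn@mHSA mt-Co1 fell from 12890 ± 1580 to 8557 ± 1800 CPM (log2 fold change -0.59) while mt-Rnr2 rose from 165.4 ± 13.3 to 439.4 ± 109 CPM (1.41), and 5 of 14 were lower and 3 higher (camera adjusted p 0.637). With P-Mn/TI@mHSA 9 were lower and 3 higher (median -0.327, camera p 0.0444, adjusted 0.13). Mitochondrial reads made up 1.773 to 2.199% of the counts in PBS, 1.31 to 1.793% in P-Mn@mHSA and 1.115 to 1.341% in P-Mn/TI@mHSA, which leaves a difference in RNA quality open. Ifnb1, the interferon beta gene, had 0, 0 and 0 counts in PBS, 4, 9 and 3 in P-Mn@mHSA and 7, 3 and 1 in P-Mn/TI@mHSA, too few to be tested.

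Interferon-stimulated genes were higher with P-Mn@mHSA and lower again with the TRAF6 inhibitor. A trend with gene length and GC content did not account for it: after removing that trend from each library the list median was 0.794 ± 0.128 (SE) against PBS, from 0.829, and -0.385 ± 0.0551 between the particles, from -0.433 (camera adjusted p 2.8e-22 and 8.11e-38 with the preset correlation). With an estimated correlation and without that correction the list was not called (0.189 and 0.059). A single library did not either, since the lowest P-Mn@mHSA library lay 0.184 above the highest P-Mn/TI@mHSA library and the camera adjusted p between the particles was 4.41e-27 or lower without any 1 library. Reads shared between paralogs were not the whole cause, since the 37 members with under 5% of their 50-mers in another gene had a median of -0.438 ± 0.0788, against -0.477 for all 53. The inhibitor may lower part of the interferon response that the particles raise, a hypothesis found and tested on the same data, and a difference between preparations or cultures stays open because replicates may be technical. The RNA quality lists of mitochondrially encoded and ribosomal protein genes were also lower between the particles (camera adjusted p 0.0117 and 0.0139). Without P-Mn@mHSA replicate 2 the ribosomal protein list turned direction. Whether RNA quality contributes to the interferon result was not tested.

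Glycolysis and hypoxia genes were higher with both particles. The list median after removing the length and GC trend was 0.584 ± 0.174 (SE) with P-Mn@mHSA, from 0.626, and 0.557 ± 0.167 with P-Mn/TI@mHSA, from 0.607 (camera adjusted p 2.1e-11 and 5.13e-09 with the preset correlation). With an estimated correlation and without that correction the list was not called (0.156 and 0.263). Over TMM, median-of-ratios, upper-quartile and total-count scaling the lowest median was 0.602 and 0.526, against 0.681 and 0.607 with TMM. The choice among these scalings therefore did not make the rise. The TMM factors were 0.9776 to 1.041, too close together for that choice to move the medians far. Each of these scalings is relative, so a change in total RNA per cell could not be seen. That the particles raise a hypoxia-like programme is a hypothesis found and tested on the same data, and measuring oxygen and HIF-1α protein in the cultures would test it. Oxygen and cell density in the cultures were not analysed here and stay open.

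In 7 genes 1 library lay at least 3-fold from both others of its group, among genes of 200 counts or more. Gapdh had 7579 counts in P-Mn@mHSA replicate 2, against 517 and 537, the pseudogene Gm2606 had 1663 in P-Mn/TI@mHSA replicate 2, against 92 and 69, and Sumo2 had 1038 in PBS replicate 2, against 140 and 299. Of the 8 gaps, 5 ran against the order of total counts within the group, so that order did not account for these 5. In the library with the middle total of its group, a gap in either direction runs against the order. Of the 5, only the gap of Sumo2 in P-Mn@mHSA replicate 1 was not in such a library. All 8 were wider than the totals of a group differ, at 3.08-fold or more (the lowest 95% counting bound was 2.44) against at most 1.04-fold, although the choice of genes at 3-fold largely fixes this second value. All 7 genes share at least 10% of their 50-mers with another gene, against 1632 of 8646 other genes (18.9%; Fisher's exact test, two-sided, p 8.66e-06), so an uneven division of shared reads between copies may be the source, and no biological explanation was tested.

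With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each comparison 1 of the 10 splits, the real one, gave as many changed genes: 5840 for P-Mn@mHSA against PBS, 6975 for P-Mn/TI@mHSA against PBS and 415 between the particles, where the highest other split gave 0, 0 and 0. Every other split mixes both groups on each side, so a difference between the groups widens its spread. Its 0 changed genes are therefore no measure of chance. For the gene lists 1 of 10 splits gave as many, with 10, 9 and 14 lists against 8, 8 and 12 in the highest other split.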
